A study of Rattus norvegicus with 18 samples.

How the data were processed

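Liver RNA of 18 adult female rats, about 1 year old, was sequenced after 3 months on 1 of 3 doses of vitamin D. The labels give the doses as 0, 1000 and 5000 U/kg and do not say whether this is per kg of body weight or of feed. The 3 groups held 6 rats each, and every library came from a separate animal. Per the labels' protocols, total RNA was isolated with the Total RNA Mini kit and libraries were built with the QuantSeq 3' mRNA-Seq kit (FWD), which reads the 3' end of polyadenylated transcripts. Such counts follow the number of transcripts and depend little on gene length, and they rest on correct annotation of each gene's 3' end.

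The deposited values were counts of reads per gene, in 1 file per library, with no normalization. Per the submitters' processing notes, FastQC, STAR, HTSeq and DESeq2 were used. Their versions, the genome build, the annotation and the strand setting are not given in the sources used here. Each file listed 30560 Ensembl rat gene IDs and 5 HTSeq summary rows. The summary rows were kept out of library sizes and tests. Reads that fell in no gene made up 7.34% to 11.8% of all rows' total, reads that fell in more than 1 gene 2.54% to 3.84%, and reads that aligned at more than 1 place 8.45% to 14.1%. The rows for low quality and for reads that did not align held 0 in all 18 libraries. Reads of multiple alignment were not assigned to genes, so counts of near-identical paralogs are uncertain, and with the strand setting not given, so are counts of overlapping and antisense genes.

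The files do not pair gene IDs with names. The RefSeq table at hand listed 47357 rat genes, of which 0 carried an Ensembl ID, so 0 of the 30560 IDs could be matched to a symbol. The 39 gene lists fixed before the data were examined, such as vitamin D metabolism, cholesterol synthesis and markers of liver cell types, could not be tested, and the list tests and their alternatives were not run. The rule for named genes fixed at the same time needed symbols and could not be applied either. In its place, the gene of smallest p in each direction was taken from each comparison with the undosed rats, among genes with a mean of at least 5 CPM over the 18 libraries, and 1 further gene was taken because DESeq2 called it. This rule was chosen after the values were seen, and the ID of 1 of the 5 genes is left out.

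Gene counts totalled 6787030 to 12555500 per library. Tests used edgeR 4.0.16 in R 4.3.3: genes with low counts were removed by edgeR's default filter by group, libraries were scaled by TMM, 1 model with the 3 dose groups and no covariate was fitted to all 18 libraries with robust quasi-likelihood dispersions, and p-values were adjusted by the Benjamini-Hochberg method over the 11268 genes tested, with a threshold of 0.05. Comparisons were 1000 against 0, 5000 against 0 and 5000 against 1000 U/kg, with an F test of any difference among the 3 groups. CPM values of single named genes were scaled by TMM and are given as mean ± SD. Sums and ratios of CPM over sets of genes in single libraries used the total gene count. Single values per library were compared by exact permutation tests, two-sided, over all splits of the libraries compared (924 for 12 libraries, 462 for 11 and 252 for 10). Principal components were computed from log2 CPM with a prior count of 2.

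The test was checked on simulated counts that had the means, dispersions and library sizes of the real libraries, with 50 genes changed at each of 4 fold sizes. Of genes changed 4-fold, the test called 74% for 1000 against 0, 64% for 5000 against 0 and 58% for 5000 against 1000 U/kg. At 2-fold these shares were 12%, 6% and 0%. Of the 101, 84 and 74 genes called in these comparisons, 9, 7 and 1 had not been changed. Each gene was drawn independently, in a single draw per comparison. The simulation leaves out that genes vary together and that single libraries stand apart, so these shares may differ in the real libraries. PCR duplicates could not be told from separate molecules, so intervals of shares cover counting error only.

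Alternatives fixed before the data were examined were DESeq2's size factors, upper-quartile scaling, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), the replicate number as a block, a fit of only the groups compared, each library left out in turn, and, for the agreement of both doses, the undosed libraries divided between the comparisons. Fits without 2 libraries with a mean Spearman correlation under 0.85 with their own group, and fits with surrogate variables (sva 3.50.0, at the number that the package estimated), were chosen after seeing the data. Each library was counted as 1 replicate, as the labels give 18 separate rats. No pair of libraries within a group held counts that agreed within sampling noise (chi-square per degree of freedom of at least 13.8), as a library deposited under both names would.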

Results

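The liver transcriptome was measured by 3' mRNA sequencing in adult female rats that had received 0, 1000 or 5000 U/kg of vitamin D for 3 months (n = 6 rats per group). The study set out to follow changes of the liver transcriptome under supplementation. Libraries of the undosed rats held 9720840 ± 1654270 gene counts (SD, n = 6), those at 1000 U/kg 9756080 ± 1105700 and those at 5000 U/kg 8083260 ± 988903. The lower depth at 5000 than at 1000 U/kg had an exact permutation p of 0.026, and that at 5000 against 0 U/kg one of 0.0541. Neither passed adjustment over the 27 such tests of library measures (adjusted p = 0.351 and 0.487, exact permutation tests). Between 13422 and 15356 genes had at least 1 count in a library.

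The livers of the 3 dose groups were not separated on the first 2 principal components, which held 37.5% and 17.7% of the variance. On these components, no difference between dose groups passed 0.05 (exact permutation p of at least 0.136 in 6 tests). A pair of single rats stood apart on them. The SD was 78.8 in undosed rats on the first component and 59.0 at 1000 U/kg on the second. With components shaped this much by single libraries, these tests could show only large differences between doses. The undosed library of replicate 2 lay at 167 on the first component, and its Spearman correlations with its own group averaged 0.698. The library of replicate 5 at 1000 U/kg lay at 129 on the second component, with a mean correlation of 0.801. The mean correlations of the other 16 libraries ranged from 0.869 to 0.942.

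**Figure D1:**
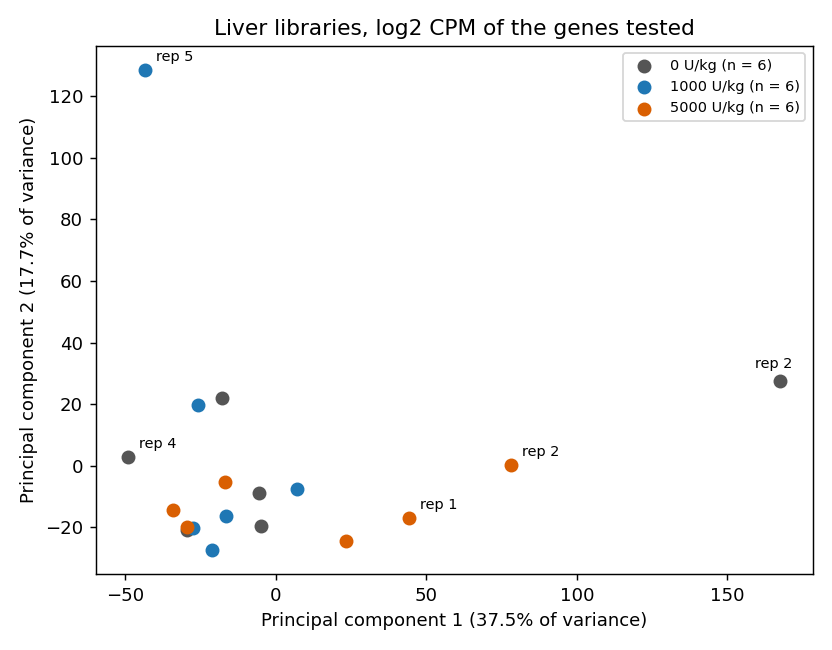
First (horizontal) and second (vertical) principal component of log2 CPM, in arbitrary units, with 1 point per liver library, coloured by dose (n = 6 per dose). The undosed replicate 2 lies at 167 on the first component and replicate 5 at 1000 U/kg at 129 on the second, while the dose groups overlap.

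In the library of replicate 5 at 1000 U/kg, 196 genes each exceeded 10 times their maximum in all other libraries. They held 7.16% of its gene counts (95% exact Clopper-Pearson interval 7.14 to 7.17), and in the other 17 libraries their summed level was 500.1 to 1319 CPM.

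**Figure D2:**
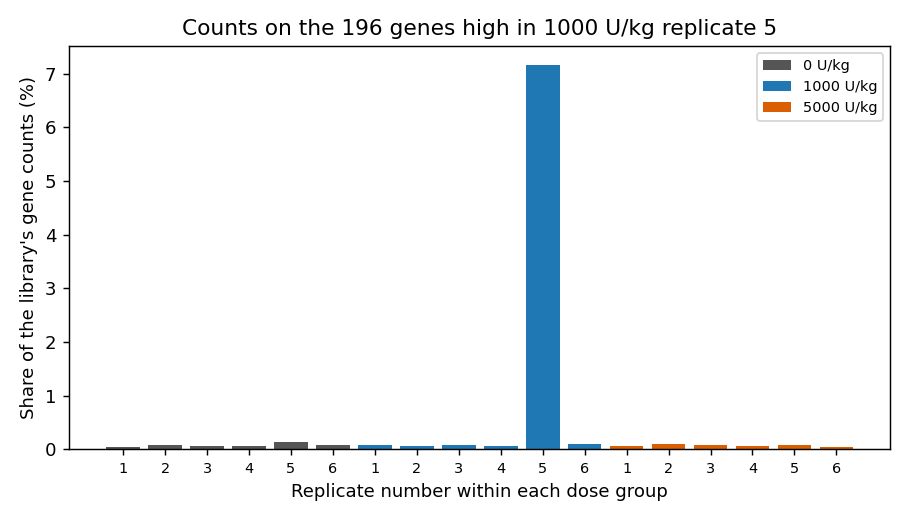
Share of each library's gene counts (vertical, %) that fell on the 196 genes, by replicate number within each dose group (horizontal), with 1 bar per library. Replicate 5 at 1000 U/kg stands at 7.16%.

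The first comparison asked which liver transcripts differ between 1000 and 0 U/kg. No gene passed the threshold: edgeR's quasi-likelihood test called 0 of 11268 genes, and the smallest Benjamini-Hochberg adjusted p was 0.644. DESeq2 and limma voom also called 0 genes. Without adjustment, 839 genes had an edgeR p under 0.05, of which 348 had a higher and 491 a lower mean at 1000 U/kg. This is more than the 563.4 of uniform p-values and no more than regrouped libraries gave: 89 of 100 splits of the same 12 libraries, the real one included, gave at least as many, and the median of the other splits was 1013. The gene of smallest p was at 2.26 ± 0.764 CPM in undosed and 351 ± 852 CPM in dosed rats (n = 6 each), a log2 fold change of 7.27 (SE 1.73, edgeR adjusted p = 0.644). That value came from replicate 5 alone, which held 2091 CPM, while the other libraries of the dose held at most 3.44 CPM. ENSRNOG00000011887 had the smallest p among genes of lower mean that averaged at least 5 CPM, with 10.0 ± 11.9 CPM in undosed rats and 2.41 ± 0.793 CPM at 1000 U/kg. Its log2 fold change was −2.05 (SE 0.50, edgeR adjusted p = 0.644), and the undosed replicate 2 alone held 33.9 CPM. Without the pair of libraries of low correlation, the log2 fold changes of these genes were 0.21 (SE 0.39) and −1.03 (SE 0.31). The same fit called 0 of 11258 genes, and 224 genes had an unadjusted p under 0.05.

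The second comparison asked the same of 5000 against 0 U/kg. The edgeR test called 0 of 11268 genes (smallest adjusted p = 0.99996), as did DESeq2 and limma voom. An unadjusted edgeR p under 0.05 was found for 400 genes, of which 143 had a higher and 257 a lower mean at 5000 U/kg. The median log2 fold change of all genes was −0.080, and −0.024 without the undosed replicate 2. ENSRNOG00000042501 averaged 9.96 ± 2.72 CPM in undosed rats, 13.9 ± 3.48 CPM at 1000 U/kg and 19.6 ± 5.04 CPM at 5000 U/kg (n = 6 each). Its log2 fold change between 5000 and 0 U/kg was 0.98 (SE 0.24, edgeR adjusted p = 0.99996), and the libraries of these doses did not overlap. ENSRNOG00000067988 averaged 6.85 ± 1.79, 4.82 ± 0.912 and 3.76 ± 0.661 CPM in the same order of doses. Its log2 fold change was −0.86 (SE 0.24, edgeR adjusted p = 0.99996), again with no overlap between 5000 and 0 U/kg. Over all genes tested, 16 did not overlap between these doses, or 0.142%, where chance gives 0.216%. Without the pair of libraries of low correlation, 0 of 11258 genes were called and 1010 had an unadjusted p under 0.05, of which 640 had a higher and 370 a lower mean at 5000 U/kg, the opposite balance to that with all libraries.

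**Figure D3:**
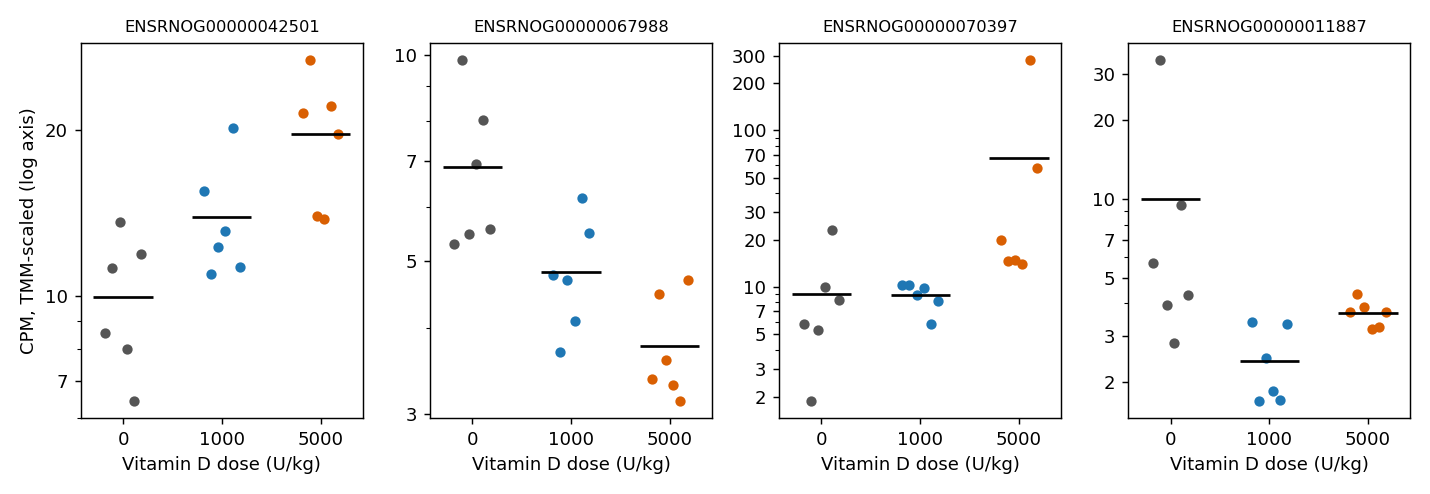
CPM (vertical, log axis) of 4 genes in each of the 18 livers by vitamin D dose in U/kg (horizontal). Points are single rats and black lines the group means (n = 6). None of these genes passed the edgeR threshold. A single rat at 5000 U/kg stands at 280 CPM for ENSRNOG00000070397 and an undosed rat at 33.9 CPM for ENSRNOG00000011887.

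Between 5000 and 1000 U/kg, the direct test of a difference between doses, edgeR called 0 of 11268 genes (smallest adjusted p = 0.628), and DESeq2 and limma voom also called 0. Of 660 genes with an unadjusted edgeR p under 0.05, 213 had a higher mean at 5000 U/kg. Without the pair of libraries of low correlation, 0 genes were called and 604 had an unadjusted p under 0.05. The balance of direction then turned, with 413 of these higher and 191 lower at 5000 U/kg.

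The test of any difference among the 3 doses likewise called 0 genes with edgeR (smallest adjusted p = 0.220), with 630 genes at an unadjusted p under 0.05, and 0 with limma voom. DESeq2's likelihood ratio test called 1 gene, ENSRNOG00000070397 (DESeq2 adjusted p = 0.0193, edgeR adjusted p = 0.232). It averaged 9.08 ± 7.42 CPM in undosed rats, 8.89 ± 1.70 CPM at 1000 U/kg and 66.8 ± 106 CPM at 5000 U/kg (n = 6 each), where replicate 5 held 280 CPM. The medians were 7.06, 9.37 and 17.5 CPM, and the ranges 1.87 to 23.1, 5.86 to 10.3 and 14.0 to 280 CPM. Over all genes tested, 20 did not overlap between 5000 and 1000 U/kg, or 0.177%, where chance gives 0.216%. Without that library the DESeq2 call was lost (DESeq2 adjusted p = 1.0), and the log2 fold change between 5000 and 0 U/kg went from 2.88 (SE 0.73) to 1.39 (SE 0.49).

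The spread between libraries of a group, in which rats and library preparation cannot be told apart, set how small a change could be seen. The biological coefficient of variation was 0.527, and 0.384 without the pair of libraries of low correlation. The approximate 95% confidence interval of the fold change lay within 2-fold either way for 41.7% of genes at 1000 against 0 U/kg. At 5000 against 0 U/kg it did so for 43.8%. It lay within 4-fold for 87.3% and 89.6%. Without the pair of libraries of low correlation, the shares within 2-fold were 62.7% and 56.9%. In simulated counts, most changes of 2-fold were not detectable with or without that pair, and a count of 0 does not show that they are absent.

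**Figure D4:**
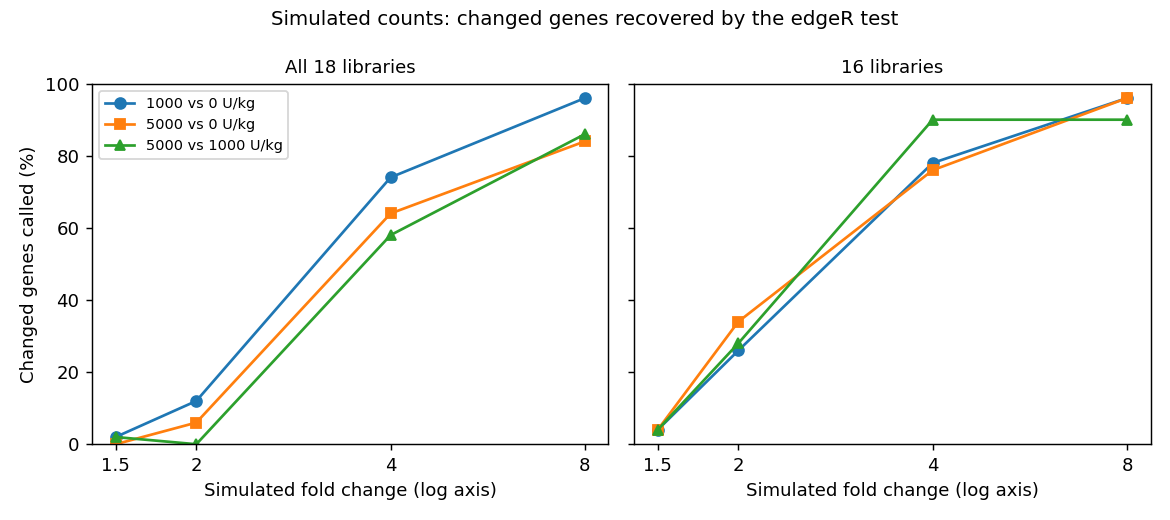
Share of simulated changed genes that the edgeR test called (vertical, %) by simulated fold change (horizontal, log axis), for each comparison, with all 18 libraries (left) and without the pair of low correlation (right). With all libraries, 74%, 64% and 58% of 4-fold changes were called, and 12%, 6% and 0% of 2-fold changes. Without the pair, 78%, 76% and 90% of 4-fold and 26%, 34% and 28% of 2-fold changes were called.

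The fold changes of both doses against the undosed rats correlated across genes with Pearson's r = 0.41 and a covariance of 0.124, where genes are not independent replicates, and 63.5% of genes had the same sign. Both comparisons use the same 6 undosed libraries. In 50 simulations with no change, all 18 libraries, the undosed ones included, were drawn from 1 common profile, each gene independently. There r was 0.50 (0.47 to 0.54) and the covariance 0.120 (0.111 to 0.134). The observed covariance lay within the simulated range and the observed r below it. The simulation leaves out that genes vary together in real libraries, so no conclusion is drawn from these positions. With single libraries left out, the observed r ranged from 0.24 to 0.66. Without the pair of libraries of low correlation, r was 0.54 and the covariance 0.0848, for which no unchanged groups were simulated. With the undosed libraries divided 3 and 3 between the comparisons, r had a median of −0.18 over 20 divisions (−0.44 to 0.04).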

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

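The splits of the libraries other than those for the fit without 2 libraries, the tests of depth and of reads outside genes in the undosed replicate 2, of genes lowered in single libraries and of 220 genes high in replicate 5 at 1000 U/kg were chosen only after the results were seen, as was the fit without 2 libraries. A sample was marked when its gap to the nearest other of its group exceeded Dixon's limit for 6 samples. Of 45 groups of values tested, 8 held such a sample, where independent values not picked from these data would give 2.25. Some groups were CPM of genes picked for a small p or a DESeq2 call, and several measures describe the same library. The excess is therefore no test against chance.

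The undosed replicate 2 stood apart in its mean Spearman correlation (0.698), on the first principal component (167.4) and in its share of reads outside genes (11.8%). It also set the level of ENSRNOG00000011887 at 33.9 CPM. Shallow sequencing is argued against, since its gene count was 1.11 times the median of the other 17 libraries. Dilution by RNA of another tissue alone is argued against too. Of 2209 genes that held at least 20 CPM in all other libraries, 138 lay below their minimum divided by 4, while the median of such genes was at 0.819 of the other libraries. In the 16 libraries of higher correlation at most 11 did, of 1862 to 1893 genes. The minima for these 16 include the undosed replicate 2, which holds their counts down, so this comparison is not between like measures. Lower RNA or library quality stays open, because over the other 17 libraries the share of reads outside genes and the component had r = 0.289 (permutation p = 0.262, Spearman's rho = 0.260, p = 0.314; r = 0.267 without the 2 farthest libraries). The undosed replicate 2 also held the highest share of reads that fell in more than 1 gene, 3.84%, where the next library held 3.53%. That share was not tested against the component of all 18 libraries. The next library on this component was replicate 2 at 5000 U/kg, at 78.2. A biological difference of the undosed rat was not tested, as the labels give none.

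Replicate 5 at 1000 U/kg stood apart in its mean correlation (0.801), on the second component (128.5) and in the gene of smallest p against 0 U/kg (2091 CPM). In this library 196 genes exceeded 10 times the maximum of all others, and they held 7.16% of its gene counts (95% exact Clopper-Pearson interval 7.14 to 7.17). Their summed CPM in the other 5 rats of the dose was 1.003 times that of undosed rats, which tests little, as they were chosen to be low there. Of 220 genes chosen only for exceeding 10 times the undosed maximum in this library, 196 were the same genes. Their summed CPM in the other 5 rats of the dose was 1.018 times that of undosed rats (873 ± 181 against 857 ± 284, exact permutation p = 0.911), with at most 1164 in one rat, which argues against a dose effect in every rat on these genes as a set. In 34 of the 220 the mean of the other 5 rats was at least 2 times the undosed mean. Genes lower by as much and the share among all genes were not counted, so these 34 are not read as a dose effect. RNA of another tissue may be the source, but with no gene names no tissue can be recognised, so this cannot be told apart from a state of this rat's liver. The median of abundant genes was at 0.6247 of the other libraries, lower than that share alone would bring, and genes that such a tissue shares with liver would not be among the 196. The 10 most abundant genes of this library held 44.8% of its gene counts, the highest share of all libraries, where the next held 37.2%. Counts taken by few genes lower the CPM of the rest, whatever their source. In this library 7 genes of at least 20 CPM elsewhere lay below the others' minimum divided by 4. The undosed replicate 1 had 11 and the rest of the 16 libraries 0. The minima in these counts include the undosed replicate 2, which holds the counts down. Dilution therefore stays open.

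Replicate 5 at 5000 U/kg held 279.9 CPM of ENSRNOG00000070397, where the next library of the dose held 57.2 CPM.

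With 0 genes called, all 100 of 100 splits of the libraries, the real grouping counted among them here and in the counts that follow, gave as many by construction, so the called genes give no test against chance. Few splits called any gene: 1 of 100 for 1000 against 0 (11 genes), 2 for 5000 against 0 (at most 931), 1 for 5000 against 1000 U/kg (70) and 3 for any dose (at most 6). The split with 931 genes points to a structure of the samples other than the dose groups. The numbers of genes at an unadjusted p under 0.05 were reached or exceeded by 89, 68, 14 and 79 of 100 splits in the same order, so chance could not be excluded for them. Without the 2 libraries of low correlation, 1010 genes had an unadjusted p under 0.05 for 5000 against 0 U/kg, against 562.9 expected. Of 100 splits of these 11 libraries, 16 gave as many, up to 3860, so chance could not be excluded here either. Of these genes, 37.1% lay under the median CPM, where a difference in depth between the groups was predicted to put most of them. Genes of low counts can reach a small p less often whatever the cause, and no reference share was taken. The difference in depth therefore stays open as a source.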

How the results depend on the processing

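The fits without 2 libraries and with surrogate variables were chosen after seeing the data; the others were planned. The count of 0 called genes held in each of the 3 comparisons under all 29 alternatives, and in the test of any dose under all but DESeq2, which called 1 gene. The genes at an unadjusted p under 0.05 moved more, from 224 to 1094 for 1000 against 0 (1923 of the 19788 genes tested with no filter), from 259 to 1010 for 5000 against 0, from 191 to 2309 for 5000 against 1000 U/kg and from 320 to 1612 for any dose. Leaving out the undosed replicate 2 gave 533, 672 and 1235 such genes in the 3 comparisons, and leaving out replicate 5 at 1000 U/kg gave 479 for 1000 against 0, 191 for 5000 against 1000 U/kg and 373 for any dose. For 5000 against 0 U/kg it was 650 without the undosed replicate 3, and 259 and 264 without replicates 1 and 6 at 5000 U/kg. For 5000 against 1000 U/kg it was 1008 without replicate 1 at 1000 U/kg, and 411 and 434 without replicates 2 and 6 at 5000 U/kg. The median log2 fold change at 5000 against 0 U/kg, −0.080, was −0.10 with DESeq2's size factors, −0.024 without the undosed replicate 2, −0.00037 with voom weights, 0.0041 without the 2 libraries and 0.015 with surrogate variables, so its size depends on that replicate and on the setting. The correlation of both doses was −0.18 with divided controls. That median hides a dependence on the undosed replicate 2. With it among the controls of 1000 U/kg, r was −0.44 to −0.20, and with it among those of 5000 U/kg −0.15 to 0.04. No unchanged groups were simulated for divided controls. With all undosed libraries in both comparisons, r was 0.24 without the undosed replicate 2 and 0.66 without replicate 5 at 1000 U/kg. These are the ends of the range over single libraries left out. With the replicate number as a block, 0 genes were called in all 4 tests, with 358, 333, 647 and 348 at an unadjusted p under 0.05. The numbers were not taken to pair the rats, since the labels do not say that they mark a litter or batch. Deviations of same-numbered libraries correlated over 0.1 in 10 of 18 pairs and below 0 in 6. Of 18 libraries, 1 correlated best with its own number in both other groups. No reference from libraries of different number was taken, so these values do not decide whether the numbers pair the rats. The named genes kept their sign under all alternatives but not their size. The log2 fold change of the gene of smallest p at 1000 against 0 U/kg, 7.27, was 1.63 with the block, 0.15 with voom weights and 0.050 (SE 0.45) with surrogate variables. With surrogate variables, ENSRNOG00000011887 went from −2.05 to −0.82 and ENSRNOG00000042501 from 0.98 to 0.60. Tests of gene lists were not run, as no ID has a name. At this depth and with 6 rats per group, the test found 64% of simulated 4-fold and 6% of 2-fold changes for 5000 against 0 U/kg, and 76% and 34% without the 2 libraries.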

Other observations

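The tests on the first component of 16 libraries were chosen after the results were seen. Among the 16 libraries without the undosed replicate 2 and replicate 5 at 1000 U/kg, the first principal component held 34.8% of the variance. The 3 highest libraries were all at 5000 U/kg, where replicates 1, 2 and 6 lay at 61.3, 95.95 and 41.1, and replicates 3, 4 and 5 at −28.3, −34.8 and −1.95. The highest library was at 11.7 in undosed rats and at 30.4 at 1000 U/kg. The component averaged 22.2 ± 52.4 at 5000 U/kg (n = 6), −11.1 ± 23.7 at 1000 U/kg (n = 5) and −15.6 ± 28.8 in undosed rats (n = 5). No difference between doses passed the test (exact permutation p = 0.184 for 5000 against 0, 0.221 for 5000 against 1000 and 0.794 for 1000 against 0 U/kg, adjusted p = 0.331, 0.331 and 0.794), so a part of the dose in this component stays open. Over these 16 libraries the component rose with the share of reads that fell in more than 1 gene (Pearson's r = 0.790, permutation p = 0.00023, adjusted p = 0.00115; Spearman's rho = 0.688, permutation p = 0.0044, adjusted p = 0.011), and r was 0.657 without the 2 libraries farthest from the median share. It fell with the share of counts taken by each library's most abundant gene (r = −0.741, permutation p = 0.00069, adjusted p = 0.00172; rho = −0.841, permutation p = 0.0001, adjusted p = 0.0005), with r = −0.851 without the 2 farthest, and with the share of reads at more than 1 place (r = −0.609, permutation p = 0.0116, adjusted p = 0.0193; rho = −0.571, permutation p = 0.0231, adjusted p = 0.0385), with r = −0.589. Total gene counts (r = −0.299, permutation p = 0.259; rho = −0.0824, permutation p = 0.764) and reads outside genes (r = 0.141, permutation p = 0.601; rho = 0.0912, permutation p = 0.737) did not pass the test. Adjustment was over these 5 measures. With all 18 libraries, the share of reads in more than 1 gene was 3.24% ± 0.218 at 5000 and 2.88% ± 0.231 at 1000 U/kg (n = 6 each, exact permutation p = 0.0238, adjusted p = 0.351 over 27 tests). Of 100 splits of the 11 undosed and 5000 U/kg libraries, the one that called most genes, 1626, put the undosed replicates 3 and 6 with replicates 1, 2 and 6 at 5000 U/kg.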
